A study of Homo sapiens with 8 samples.

How the data were processed

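RNA from MCF7 cells, an estrogen-receptor-positive human breast cancer line, was measured on 8 Affymetrix Gene 1.0 ST arrays, 1 array per culture plate. Per the labels' protocols, cells were grown in phenol-red-free medium with 5% charcoal-stripped supplement, which is low in steroid hormones. They were transfected with a control siRNA or an siRNA against cyclin D1, kept for 48 h, then given vehicle or estradiol for 24 h. RNA was extracted with Trizol, cleaned on a Qiagen column and turned into biotinylated cDNA by the NuGEN protocol, per the labels. The dose of estradiol and the sequence of each siRNA are not given in the sources used here. The titles place the arrays in 4 groups of 2, and the series design text describes separate plates, so the replicates are separate plates of 1 cell line. Their p-values measure the spread between such plates only.

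The table deposited by the authors holds log2 values for 28869 probe sets on the 8 arrays. Per the submitters' processing notes the arrays were handled in Affymetrix Expression Console 1.1; the summarization and normalization settings and the genome build are not given in the sources used here. The base of the logarithm is not stated and was taken as 2, the usual base for this software, so every fold given rests on that reading. In each of the 28869 rows the median over the 8 arrays was 0 within 1e-06, so each probe set had been centred on its own median. The values ran from -2.75 to 4.50 with 0 missing. Centring leaves differences between arrays untouched but removes the brightness of each probe set, so signal over background cannot be given. Whether dim signal or the number of arrays limits the precision was not tested. The medians of the 8 arrays lay between -0.027 and 0.034.

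Genes were named from the platform annotation, with symbols updated through Entrez identifiers in the RefSeq table of assembly GRCh38.p14, which was used for names only. Of the probe sets, 19310 had 1 gene symbol, 1752 had several and 7807 had no gene listed. Probe sets with 1 symbol gave 18377 genes, of which 18348 had an Entrez identifier in that table. The fixed plan was to take the brightest probe set for each gene. Because the centred values hold no brightness, the probe sets of the 685 genes with over 1 were averaged instead, a choice made after the form of the values was seen, and the planned pair was turned round, with the probe set of highest mean centred value as the alternative. For the same reason the planned filter on dim probe sets was not run, and quantile normalization and a variance trend, both run as alternatives, acted on centred values. The planned change of pseudocount did not apply to log values.

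Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes without a trend on 4 group means and all 8 arrays, 2-sided, with Benjamini-Hochberg adjustment over the 18377 genes within each comparison. Genes with an adjusted p under 0.05 are said to have passed. The fit had 4 residual degrees of freedom and 26.9 prior degrees of freedom. The 6 comparisons were the cyclin D1 siRNA difference averaged over vehicle and estradiol, that difference in vehicle and in estradiol, the estradiol difference in control and in cyclin D1 siRNA, and the interaction, which is the estradiol response in cyclin D1 siRNA minus that in control siRNA. Errors beside log2 differences are standard errors (SE) of the fit, with 2 arrays per group and 4 per siRNA for the average. Arrays were simulated with the same number of genes, 200 of them changed, and noise drawn for each gene on its own. On these the averaged difference recovered 94.0% of genes changed by a log2 of 1. The estradiol comparison recovered 46.3% of such genes. The interaction recovered 14.9% of them, and 90.9% of those changed by a log2 of 2. In the real estradiol comparison in control siRNA 35.9% of genes passed, so its threshold was looser than the simulated one. Noise in the real arrays can also be shared between genes, so these shares do not give the power of the real comparisons.

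The text names genes by a rule set before the data were examined, as were the gene lists and the comparisons. CCND1 is named throughout. For the averaged difference, the estradiol response in control siRNA and the interaction, up to 8 passing genes with the largest rise and 8 with the largest fall were taken. For the other comparisons up to 4 each way were taken. Except in the interaction, the arrays of the groups compared had to lie apart without overlap. Where fewer than 3 passed in a direction, the 3 with the smallest p were taken. Members of the lists were taken by smallest p, up to 4 a list. Genes with uncertain symbols, immunoglobulin and olfactory receptor genes and small RNAs were counted but not named among the largest changes.

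The 19 lists held 536 written members, 493 of them measured. They covered estrogen-induced, estrogen-repressed, DNA replication and E2F target, mitotic, D-type cyclin with CDK and CDK inhibitor, p53 target, interferon-stimulated, luminal epithelial, basal and mesenchymal, leukocyte, cholesterol synthesis, unfolded protein and amino acid stress, glycolysis, oxidative phosphorylation, hypoxia-induced, growth factor and cytokine, DNA repair and checkpoint, immediate-early and stress, and housekeeping genes. CCND1 is in none of them. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 19 lists within a comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way, were run beside it. Counts of list members are given over all genes tested and adjusted over the list alone.

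The alternatives tried were quantile normalization, array quality weights, eBayes with trend and robust moderation, the replicate number as a block, only the groups compared in the fit, at least a 1.5-fold change, and leaving out each array in turn. When that leaves 1 array in a group, the lone array is assumed to vary like the other groups. Alternatives added after seeing the data were equal array medians and the main axis of the differences between replicates as a covariate. That axis was drawn from the residual spread of these same arrays and takes out its largest part. SE and p-values from that fit therefore tend to be too small, except where the axis runs with the groups compared. The median SE of the averaged difference was 0.157 with it and 0.191 without. The closing section gives the effect of all alternatives. Probe sets with several symbols or no gene listed were tested separately and are not named.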

Results

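The 8 arrays covered a 2 by 2 design in MCF7 cells, with control or cyclin D1 siRNA and vehicle or estradiol, the main estrogen, and 2 arrays in each of the 4 groups. The series asks whether cyclin D1 determines estrogen-dependent signalling. Expression is given as log2 values with each probe set's median over the 8 arrays at 0, so only differences between arrays carry information. Across all named genes, replicates differed by a median of 0.21 in control siRNA with vehicle, 0.24 in control siRNA with estradiol, 0.34 in cyclin D1 siRNA with vehicle and 0.25 in cyclin D1 siRNA with estradiol. The first principal component held 59.8% of the variance. It placed the control vehicle arrays at -53.3 and -39.2 and the control estradiol arrays at 62.9 and 43.3. The cyclin D1 siRNA vehicle arrays lay apart from each other on it, at -49.0 for replicate 1 and -10.4 for replicate 2.

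CCND1, which encodes cyclin D1, the siRNA's target and a partner of CDK4 and CDK6 in G1, was measured on every array. Its log2 values were 1.13 and 1.15 in control siRNA with vehicle, and 0.24 and -0.44 in cyclin D1 siRNA with vehicle. In vehicle CCND1 therefore fell 2.36-fold with the siRNA (log2 -1.24 ± 0.28 SE, n = 2 arrays per group, limma adjusted p = 0.0326). In estradiol the values were -0.38 and 0.19 with control siRNA and -0.19 and -0.26 with cyclin D1 siRNA. The difference there was -0.13 ± 0.28 (95% interval -0.70 to 0.43, adjusted p = 0.849), so a knockdown at the RNA level was not detectable in estradiol. Averaged over both treatments CCND1 differed by -0.69 ± 0.20 and did not pass (adjusted p = 0.0803). CCND1 fell by 1.23 with estradiol in control siRNA (adjusted p = 0.00123), and its estradiol difference in cyclin D1 siRNA was -0.12 ± 0.28 (adjusted p = 0.819). The interaction for CCND1 was 1.11 ± 0.39 and did not pass (adjusted p = 0.345). The averaged difference passed without control estradiol replicate 1, at -0.83, and without cyclin D1 vehicle replicate 1, at -0.86. The call in vehicle was lost without either control vehicle array or without cyclin D1 vehicle replicate 2, with log2 differences over all such fits of -1.58 to -0.90. With the main axis of replicate differences as a covariate it was lost too (-0.99 ± 0.23, adjusted p = 0.189), as was the fall with estradiol in control siRNA (-0.44 ± 0.36, adjusted p = 0.630).

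**Figure D1:**
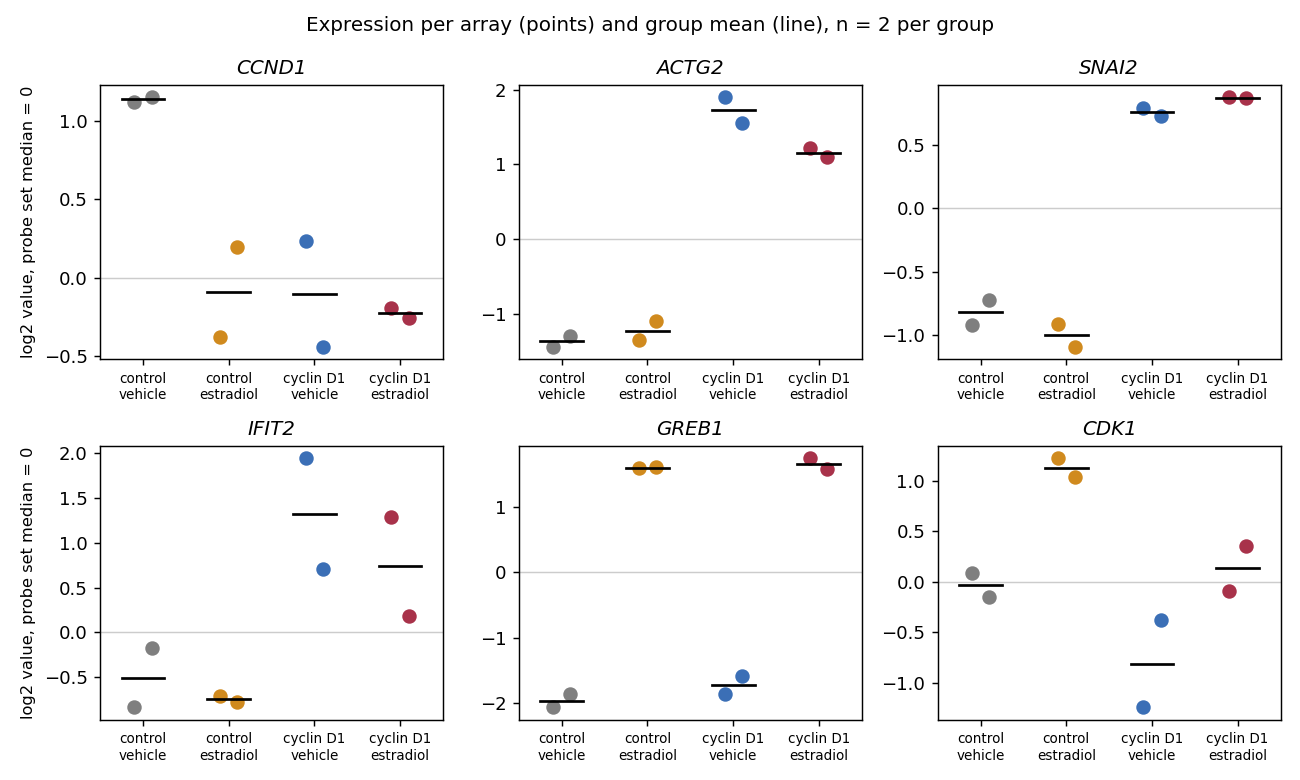
Log2 values of 6 genes, with each probe set's median at 0, on each array (points, 2 per group) and as group means (lines). CCND1 lay at 1.13 and 1.15 in control siRNA with vehicle and between -0.44 and 0.24 in the other groups, ACTG2 and SNAI2 separated the siRNAs under both treatments, and GREB1 separated vehicle from estradiol under both siRNAs.

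With cyclin D1 siRNA, averaged over vehicle and estradiol, the smooth muscle actin gene ACTG2 rose 6.67-fold (log2 2.74 ± 0.19 SE, n = 4 arrays per siRNA). DIO2, a deiodinase that activates thyroid hormone, rose 3.52-fold (1.81 ± 0.19), and SNAI2, a transcription factor of epithelial-mesenchymal transition, rose 3.30-fold (1.72 ± 0.18). The growth factor TGFB2 rose by 1.55 ± 0.19, ANKRD1, a target of YAP signalling, by 1.73 ± 0.22, and the long noncoding RNA HCP5 by 1.55 ± 0.22. MSMB, which encodes a secreted microseminoprotein, fell 2.91-fold (-1.54 ± 0.19), followed by TEKT2, a tektin of cilia and flagella (-1.29 ± 0.20), NDRG1 (-1.21 ± 0.20) and the histone gene H4C2 (-1.21 ± 0.20). ACTL8 (-1.13), the chromatin remodeller HELLS (-1.04), DHRS2 (-1.04) and the pseudogene VN1R10P (-0.97) also fell. The averaged falls were not even over the treatments. MSMB fell further in estradiol, and NDRG1 and H4C2 fell further in vehicle, as given below. In all, 211 of 18377 genes passed, 146 higher and 65 lower, with 2809 at an unadjusted p under 0.05. Because 1 siRNA was used for each group, differences between the siRNAs cannot be told apart from effects of the duplex itself. This holds for the average and for each treatment below.

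Interferon-stimulated genes made up the group with the largest shift. Of 36 measured members 23 rose and 0 fell, or 30 and 0 adjusted over the list alone, with a median log2 difference of 0.89 (camera adjusted p = 3.03e-38, adjusted p = 0.168 with an estimated correlation). The list did not pass by fry (fry adjusted p = 0.0877), nor in vehicle (fry adjusted p = 0.217) or estradiol alone (fry adjusted p = 0.118). IFIT2 rose 3.16-fold (1.66 ± 0.24) and IFIT3 2.56-fold (1.36 ± 0.21), both antiviral genes. SAMD9L, an antiviral gene outside the list, rose by 1.75 ± 0.25. IFI6 (-0.07 ± 0.25) and EPSTI1 (-0.20 ± 0.19) did not pass. The list differed between replicates too, with array medians of 0.92 and 0.42 in cyclin D1 siRNA with vehicle and 0.65 and 0.05 with estradiol, against -0.15 and -0.04 in control siRNA with vehicle and -0.66 and -0.58 with estradiol. The 12 leukocyte genes had a median of -0.12, with 0 passing in either direction and 1 higher adjusted over the list alone (camera adjusted p = 0.683). The count of risers was 5 without control vehicle replicate 1 and 8 without replicate 2, with medians of 0.85 and 0.92. It was 10 without cyclin D1 vehicle replicate 1 (median 0.74) and 5 without cyclin D1 estradiol replicate 1 (median 0.69), each the array with the higher interferon median of its pair.

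Cell cycle lists passed toward lower values with cyclin D1 siRNA. Of 50 DNA replication and E2F target genes 0 rose and 7 fell, or 41 fell adjusted over the list alone, with a median of -0.52 (camera adjusted p = 6.93e-25, adjusted p = 0.162 with an estimated correlation). The members that fell included the helicase gene BLM (-0.83 ± 0.19), the replication licensing gene CDC6 (-0.79 ± 0.18), DSCC1 (-0.93 ± 0.22) and the exonuclease gene EXO1 (-0.79 ± 0.19). Of 43 mitotic genes 0 rose and 1 fell, CDK1, the kinase that drives entry into mitosis (-0.89 ± 0.20), or 32 fell adjusted over the list alone, with a median of -0.52 (camera adjusted p = 9.25e-19, adjusted p = 0.303 with an estimated correlation). CKS1B (-0.70 ± 0.18), NDC80 (-0.73 ± 0.20) and MYBL2 (-0.68 ± 0.19) did not pass over all genes. By fry the DNA replication list passed (fry adjusted p = 0.0227) and the mitotic list did not (fry adjusted p = 0.0877). Of 24 DNA repair and checkpoint genes 0 passed, or 7 fell adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.00135, adjusted p = 0.345 with an estimated correlation). Among 15 D-type cyclin, CDK and CDK inhibitor genes RBL2, a relative of the retinoblastoma gene, rose (0.82 ± 0.19) and 0 fell, or 2 and 2 adjusted over the list alone (median 0.05, camera adjusted p = 0.330). BLM, CDC6, DSCC1, EXO1, CDK1 and RBL2 each lost their call in at least 4 of the 8 fits that left out 1 array, among them the fits without control vehicle replicate 1 or 2 and without cyclin D1 estradiol replicate 1. The count of falling DNA replication genes was 0 without either control vehicle array and 1 without cyclin D1 estradiol replicate 1. It was 2 without control estradiol replicate 1, and 3 and 11 without cyclin D1 vehicle replicate 1 and 2. Falling mitotic genes numbered 7 without cyclin D1 vehicle replicate 2 (median -0.67), and 0 without replicate 1 (median -0.38), cyclin D1 estradiol replicate 1 or either control vehicle array. They numbered 2 without control estradiol replicate 1 or cyclin D1 estradiol replicate 2. The DNA repair call was lost without cyclin D1 vehicle replicate 1 (median -0.24, camera adjusted p = 0.0595).

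Metabolic and signalling lists moved less. Of 19 hypoxia-induced genes 0 rose and 3 fell, or 7 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 2.07e-05, adjusted p = 0.168 with an estimated correlation). They included NDRG1 and BNIP3, a mitophagy receptor (-0.90 ± 0.19). Of 17 glycolysis genes 2 fell, ENO2 (-0.86 ± 0.18) and ALDOC (-0.92 ± 0.20), or 3 adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.0345, adjusted p = 0.404 with an estimated correlation). Of 29 growth factor and cytokine genes 4 rose, among them TGFB2 and the cytokine gene IL6 (1.29 ± 0.20), or 5 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.00161, adjusted p = 0.162 with an estimated correlation). Of 17 immediate-early and stress genes 2 rose, the phosphatase gene DUSP1 (1.18 ± 0.20) and KLF6 (0.82 ± 0.19), or 4 higher and 1 lower adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.0362, adjusted p = 0.388 with an estimated correlation). The 45 estrogen-induced genes had a median of -0.09, with HSPB8 higher (0.90 ± 0.19) and STC2 lower (-0.82 ± 0.18), or 1 and 1 adjusted over the list alone (camera adjusted p = 0.951). TGFB2 was the 1 estrogen-repressed gene of 30 that rose, with 0 falling and the same counts adjusted over the list alone (median 0.07, camera adjusted p = 0.0680). Leaving out 1 array ended the glycolysis call in 3 fits, without control estradiol replicate 2, cyclin D1 vehicle replicate 2 or cyclin D1 estradiol replicate 2, with medians of -0.29 to -0.07 over all 8. The immediate-early call was lost in 4 fits, without control vehicle replicate 2, control estradiol replicate 1, cyclin D1 vehicle replicate 1 or cyclin D1 estradiol replicate 2, with medians of 0.00 to 0.29 over all 8. Falling hypoxia-induced genes numbered 1 without either control vehicle array or cyclin D1 estradiol replicate 1, and rising growth factor and cytokine genes 2 without control vehicle replicate 1. ENO2, ALDOC, BNIP3, HSPB8, STC2 and KLF6 also lost their calls in at least 3 such fits.

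The remaining lists did not pass for the averaged difference. Medians were 0.14 for 18 luminal epithelial genes (adjusted p = 0.105) and -0.03 for 18 basal and mesenchymal genes, of which 2 rose, or 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.223). The 28 p53 target genes had a median of 0.08 (adjusted p = 0.223), 19 cholesterol synthesis genes -0.08 (adjusted p = 0.223) and 37 oxidative phosphorylation genes -0.03 (adjusted p = 0.951). For 25 unfolded protein and amino acid stress genes the median was 0.11, with 1 higher, or 2 adjusted over the list alone (adjusted p = 0.0571). The 11 housekeeping genes stood at -0.02 (adjusted p = 0.90). The luminal epithelial list passed without control estradiol replicate 2 (median 0.24, adjusted p = 0.0279), cyclin D1 vehicle replicate 2 (0.26, adjusted p = 0.0223) or cyclin D1 estradiol replicate 2 (0.23, adjusted p = 0.0345). The unfolded protein list passed without control vehicle replicate 2 (adjusted p = 0.0494) or cyclin D1 estradiol replicate 1 (adjusted p = 0.0277). Of the 31 named genes that passed, 18 kept their call in every fit that left out 1 array, ACTG2, DIO2, SNAI2, TGFB2, IFIT2, IL6, DUSP1 and MSMB among them. The number of passing genes was 41 without control vehicle replicate 1, 65 without control vehicle replicate 2 and 65 without cyclin D1 estradiol replicate 1.

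**Figure D2:**
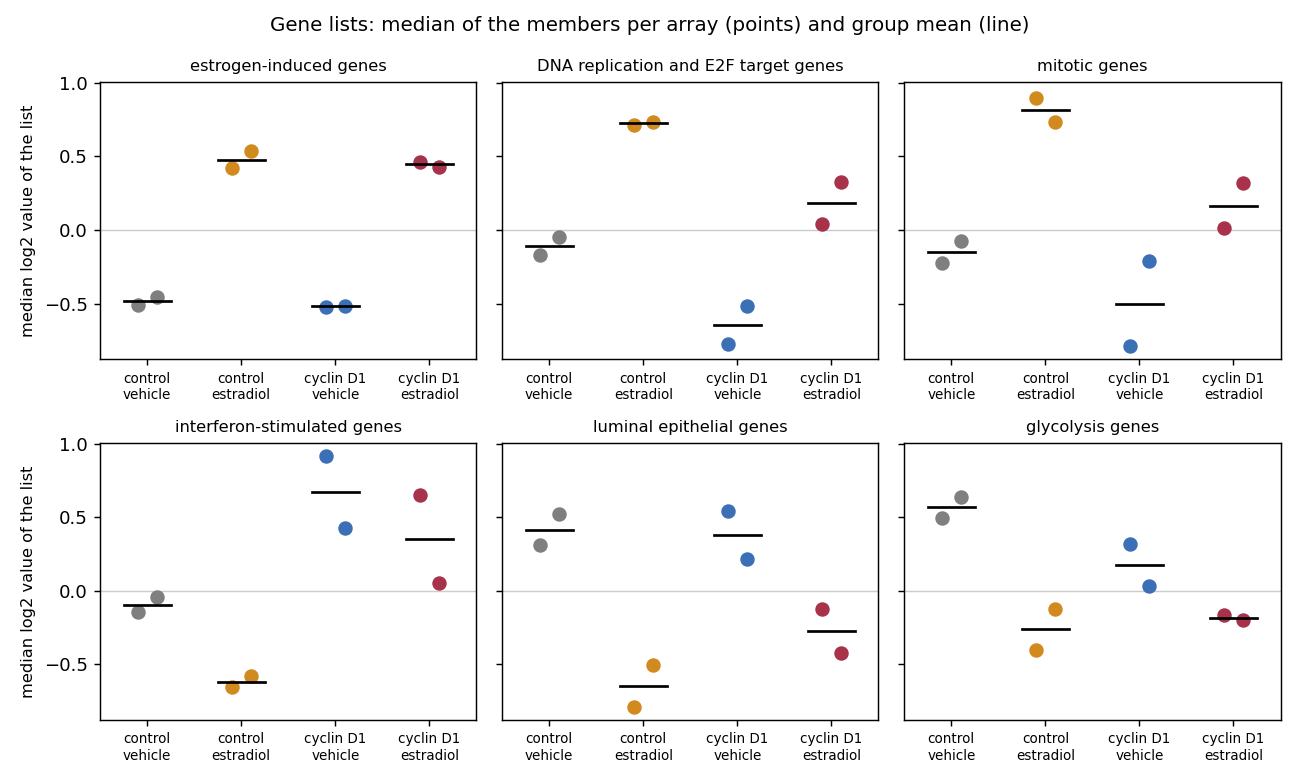
Median log2 value of the measured members of 6 gene lists on each array (points, 2 per group) and the mean of each pair (lines), with each probe set's median at 0. Estrogen-induced medians lay between -0.52 and -0.45 in the vehicle arrays and between 0.42 and 0.54 in the estradiol arrays of both siRNAs, and mitotic medians differed between the cyclin D1 vehicle replicates (-0.79 and -0.21).

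In vehicle alone, cyclin D1 siRNA raised ACTG2 8.54-fold (log2 3.09 ± 0.26 SE, n = 2 per group), SAMD9L 3.97-fold (1.99 ± 0.35), IFIT2 3.56-fold (1.83 ± 0.34) and DIO2 3.52-fold (1.81 ± 0.27). The histone genes H3C7 (-2.19 ± 0.33), H3C8 (-2.01 ± 0.27) and H4C2 (-1.98 ± 0.28) and TIMM17B, a subunit of the mitochondrial import machinery (-2.19 ± 0.45), fell most. Many histone genes are similar in sequence, so these probe sets could read more than 1 of them, which was not checked. NDRG1 fell (-1.85 ± 0.28), TGFB2 rose (1.61 ± 0.27), RBL2 rose (1.15 ± 0.27), and the replicative helicase gene MCM2 fell (-1.25 ± 0.28). In all 77 genes passed, 41 higher and 36 lower.

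Interferon-stimulated genes had a median of 0.83 in vehicle, with 4 of 36 higher, XAF1 among them (1.34 ± 0.29), or 22 higher and 2 lower adjusted over the list alone, and IFI6 (-1.35 ± 0.36) and ISG15 (-0.86 ± 0.38) did not pass (camera adjusted p = 5.98e-18, adjusted p = 0.401 with an estimated correlation). DNA replication and E2F target genes had a median of -0.61, with 1 lower, or 24 adjusted over the list alone (camera adjusted p = 7.07e-19, adjusted p = 0.310 with an estimated correlation). Mitotic genes had a median of -0.44, with 0 passing, or 1 lower adjusted over the list alone (camera adjusted p = 1.04e-07, adjusted p = 0.521 with an estimated correlation). Without cyclin D1 vehicle replicate 2 their median was -0.70. Glycolysis genes had a median of -0.58, with 0 passing, or 6 lower adjusted over the list alone (camera adjusted p = 4.13e-06, adjusted p = 0.401 with an estimated correlation). Their median was -0.37 without cyclin D1 vehicle replicate 2 and -0.59 without replicate 1. The cholesterol synthesis (median -0.33) and hypoxia-induced (median -0.27) lists also passed. In these 0 and 1 members were lower, or 1 and 2 adjusted over the list alone. By camera with an estimated correlation they had adjusted p = 0.519 and adjusted p = 0.401. Without cyclin D1 vehicle replicate 1 the cholesterol synthesis median was -0.55. Of the 14 named genes that passed, ACTG2 alone kept its call in every fit that left out 1 array. The number of passing genes was 1 and 18 without control vehicle replicate 1 and 2, 153 without either control estradiol array, and 208 and 12 without cyclin D1 vehicle replicate 1 and 2, and the mitotic call was lost without cyclin D1 vehicle replicate 1 (median -0.14). The cholesterol synthesis call was lost without control vehicle replicate 2 (median -0.32) or cyclin D1 vehicle replicate 2 (-0.10), and with the axis of replicate differences as a covariate (-0.16, camera adjusted p = 0.0619). With that covariate 1 gene passed in vehicle and 0 interferon-stimulated genes, and the DNA repair (-0.40) and oxidative phosphorylation lists (-0.19) passed. The hypoxia-induced call was lost without control vehicle replicate 2 (-0.10) or cyclin D1 vehicle replicate 1 (-0.30). Without cyclin D1 vehicle replicate 1, 0 interferon-stimulated genes rose and 2 fell (median 0.58), and without replicate 2 1 rose (median 0.97). Risers of that list numbered 0 without either control vehicle array, 11 without either control estradiol array and 8 without either cyclin D1 estradiol array. Falling DNA replication genes numbered 4 without either control estradiol array or cyclin D1 vehicle replicate 1, and 0 without either control vehicle array or cyclin D1 vehicle replicate 2. DNA repair genes passed as a list without control vehicle replicate 1 (median -0.37, camera adjusted p = 0.00899) or cyclin D1 vehicle replicate 2 (-0.46, camera adjusted p = 0.000169). The basal and mesenchymal (0.06) and growth factor lists (0.07) passed without control vehicle replicate 1, and oxidative phosphorylation genes (-0.16) without cyclin D1 vehicle replicate 2.

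In estradiol, cyclin D1 siRNA raised ACTG2 5.22-fold (2.38 ± 0.26 SE, n = 2 per group), the secreted glycoprotein gene LGALS3BP 3.89-fold (1.96 ± 0.32), SNAI2 3.65-fold (1.87 ± 0.26) and DIO2 3.52-fold (1.81 ± 0.27). MSMB fell 5.33-fold (-2.41 ± 0.27), TEKT2 3.65-fold (-1.87 ± 0.29), ACTL8 2.81-fold (-1.49 ± 0.26) and VN1R10P 2.74-fold (-1.45 ± 0.27). Among estrogen-induced genes STC2, which encodes a secreted glycoprotein, fell (-1.25 ± 0.26) and HSPB8 (0.85 ± 0.27) and the progesterone receptor gene PGR (0.73 ± 0.26) did not pass. In all 53 genes passed, 32 higher and 21 lower. CCND1 itself did not differ detectably in estradiol, so these changes are not shown to follow from loss of cyclin D1. The changes overlapped with those in vehicle, with which they share no array. Of the genes that rose, 15 did so under both treatments, against 0.0714 expected if genes were independent (Fisher's exact test p = 5.01e-33). Interferon-stimulated genes move together, and both comparisons took each gene's spread from the same fit, so neither value is a chance level. Under both treatments 0 genes fell (0.0411 expected if genes were independent). Of the 36 genes that fell in vehicle, 20 had the same sign in estradiol, as had all 41 that rose.

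Interferon-stimulated genes had a median of 0.93 in estradiol, with 9 of 36 higher, or 30 adjusted over the list alone (camera adjusted p = 2.19e-29, adjusted p = 0.199 with an estimated correlation). BST2, a membrane tether of viruses (1.60 ± 0.29), and TAP1, a transporter of antigen peptides (1.59 ± 0.30), rose. Mitotic genes had a median of -0.61, with 0 passing, or 17 lower adjusted over the list alone (camera adjusted p = 1.21e-14, adjusted p = 0.302 with an estimated correlation). CDK1 was among these, 1.99-fold lower. DNA replication and E2F target genes had a median of -0.55, with 0 passing, or 7 lower adjusted over the list alone (camera adjusted p = 9.45e-11, adjusted p = 0.199 with an estimated correlation). Further lists that passed were immediate-early and stress (median 0.31, DUSP1 higher at 1.48 ± 0.28), hypoxia-induced (-0.38), luminal epithelial (0.35), growth factor and cytokine (0.22, TGFB2 higher at 1.48 ± 0.27), DNA repair and checkpoint (-0.32) and estrogen-repressed genes (0.20). With an estimated correlation the adjusted p of all 9 passing lists lay between p = 0.199 and p = 0.339. Of the 14 named genes that passed, ACTG2, SNAI2, DIO2 and MSMB kept their call in every fit that left out 1 array. The number of passing genes was 12 without either control vehicle array, 23 and 154 without control estradiol replicate 1 and 2, and 11 without cyclin D1 estradiol replicate 1, and 2 when only these 4 arrays entered the fit. The luminal epithelial call was lost without control estradiol replicate 1 (median 0.18) or cyclin D1 estradiol replicate 1 (0.21), and the estrogen-repressed call without control estradiol replicate 2 (0.20) or cyclin D1 estradiol replicate 1 (0.12). Rising interferon-stimulated genes numbered 1 without either control vehicle array, 0 without control estradiol replicate 1 (median 0.94) or cyclin D1 estradiol replicate 1 (0.64), 5 without either cyclin D1 vehicle array and 15 without cyclin D1 estradiol replicate 2 (1.22). With the axis of replicate differences as a covariate 3 genes passed in estradiol and 0 interferon-stimulated genes (median 0.77). The luminal median was then 0.18 and the growth factor and cytokine one 0.14, with 0 members passing in either and both list calls held.

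Estradiol in control siRNA raised GREB1, an estrogen receptor cofactor and target, 11.8-fold (log2 3.56 ± 0.26 SE, n = 2 per group), and the MYB-family gene MYBL1 9.03-fold (3.17 ± 0.26). RBM24, an RNA-binding protein gene (3.05 ± 0.28), the chemokine gene CXCL12 (2.85 ± 0.26), PCP4 (2.84 ± 0.27), the protease gene PRSS23 (2.65 ± 0.26), RBP7 (2.46 ± 0.30) and MSMB (2.46 ± 0.27) also rose. The interferon-stimulated genes IFI6 (17.9-fold, -4.16 ± 0.36) and ISG15 (14.3-fold, -3.84 ± 0.38) fell most, then TIMM17B (-3.69 ± 0.45), the linker histone gene H1-4 (-3.61 ± 0.36) and PSCA (-3.43 ± 0.33). ATP6V0B, a proton pump subunit gene (-3.25 ± 0.32), S100A16 (-3.19 ± 0.31) and the tight junction gene CLDN4 (-3.18 ± 0.37) followed. In all 6595 genes passed, 35.9% of those tested, 3183 higher and 3412 lower.

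Of 45 estrogen-induced genes 32 rose and 5 fell, or 33 and 5 adjusted over the list alone, with a median of 0.99 (camera adjusted p = 4.73e-10, adjusted p = 0.132 with an estimated correlation). The members that fell included ANXA9 (-1.34 ± 0.27) and CTSD, a lysosomal protease gene (-1.24 ± 0.33). Of 30 estrogen-repressed genes 15 fell, PSCA and the ephrin gene EFNA1 (-2.18 ± 0.27) among them, and 4 rose, among them the nuclear receptor gene NR5A2 (1.99 ± 0.28) and RASGRP1 (1.73 ± 0.27), or 16 and 4 adjusted over the list alone. Their median was -0.67 (camera adjusted p = 0.000510, adjusted p = 0.132 with an estimated correlation). Of 43 mitotic genes 35 rose, among them the kinetochore genes CENPE (1.79 ± 0.28) and SPC25 (1.51 ± 0.28), and 1 fell, AURKB (-0.95 ± 0.26), or 36 and 1 adjusted over the list alone. Their median was 0.97 (camera adjusted p = 4.73e-10, adjusted p = 0.430 with an estimated correlation). Of 50 DNA replication and E2F target genes 31 rose, among them ORC6 (1.63 ± 0.27) and POLE2 (1.58 ± 0.26), and 7 fell, among them the thymidine kinase gene TK1 (-2.07 ± 0.30) and the licensing gene CDT1 (-1.27 ± 0.26), or 35 and 7 adjusted over the list alone. Their median was 0.88 (camera adjusted p = 4.20e-06, adjusted p = 0.430 with an estimated correlation). Of 24 DNA repair and checkpoint genes 16 rose, TIPIN (1.19 ± 0.27) and RAD51C (1.16 ± 0.27) among them, and 2 fell, H2AX (-1.47 ± 0.28) and XRCC3 (-0.69 ± 0.27), or 18 and 3 adjusted over the list alone. Their median was 0.87 (camera adjusted p = 0.000212, adjusted p = 0.430 with an estimated correlation). Of 15 D-type cyclin, CDK and CDK inhibitor genes 5 rose and 7 fell, or 5 and 8 adjusted over the list alone, with CDKN1A (-1.84 ± 0.27), CDKN1C (-1.35 ± 0.27), CDKN2D (-1.27 ± 0.27) and CCND3 (-1.25 ± 0.28) lower and no pass for the list (camera adjusted p = 0.209).

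Luminal epithelial genes were lower, with 11 of 18 falling and 0 rising, the same counts adjusted over the list alone and a median of -1.33 (camera adjusted p = 3.38e-06, adjusted p = 0.430 with an estimated correlation). CLDN4 and the transcription factor gene SPDEF (-2.38 ± 0.28) fell, while EPCAM (0.41 ± 0.26) and PRLR (0.38 ± 0.27) did not pass. Of 36 interferon-stimulated genes 13 fell and 0 rose, the same adjusted over the list alone. Their median was -0.45 (camera adjusted p = 5.86e-05, adjusted p = 0.511 with an estimated correlation). Of 17 glycolysis genes 8 fell, ENO1 (-2.34 ± 0.27) and ALDOA (-2.24 ± 0.29) among them, and 4 rose, PFKP (1.02 ± 0.26) and ENO2 (0.73 ± 0.26) among them, or 10 and 4 adjusted over the list alone. Their median was -0.60 (camera adjusted p = 0.00430, adjusted p = 0.430 with an estimated correlation). Of 17 immediate-early and stress genes 9 fell, JUNB (-2.58 ± 0.27) and IER2 (-2.46 ± 0.28) among them, and 2 rose, MYC (1.41 ± 0.27) and JUN (0.75 ± 0.26), the same adjusted over the list alone. Their median was -0.70 (camera adjusted p = 0.00843, adjusted p = 0.430 with an estimated correlation). Of 19 cholesterol synthesis genes 10 fell, EBP (-1.77 ± 0.29) and LSS (-1.80 ± 0.31) among them, and 4 rose, ACAT2 (1.28 ± 0.26) and HMGCS1 (1.16 ± 0.27) among them, or 11 and 5 adjusted over the list alone. Their median was -0.84 (camera adjusted p = 0.0384, adjusted p = 0.470 with an estimated correlation). The number of passing genes was 2424 without control vehicle replicate 1 and 3338 without control estradiol replicate 1. Of the 50 named genes that passed 42 kept their call in every fit that left out 1 array, and CTSD, AURKB, CCND3, HMGCS1, PFKP, ENO2, XRCC3 and JUN did not. With the main axis of replicate differences as a covariate, the estrogen-induced median was 1.01 (3 members higher) and the estrogen-repressed one -0.65. The mitotic median was then 0.32, the DNA replication one 0.53 and the luminal one -0.60. The DNA repair median was 0.57, the immediate-early one -0.32 and the glycolysis one -0.43. In each of these lists, and among the estrogen-repressed genes, 0 members passed. IFI6 stood at -2.32 ± 0.41 and did not pass. The interferon median turned to 0.16 (camera adjusted p = 0.428) and the cholesterol synthesis median was -0.20 (camera adjusted p = 0.270), so both calls were lost. The cholesterol synthesis call was lost without control vehicle replicate 2 (median -0.78) or control estradiol replicate 1 (-0.54). Without control vehicle replicate 1 the risers numbered 21 of the estrogen-induced, 18 of the DNA replication, 13 of the mitotic and 5 of the DNA repair genes. Rising mitotic genes numbered 20 without control estradiol replicate 1. Falling estrogen-induced genes numbered 1 and 3 without control vehicle replicate 1 and 2 and 2 without control estradiol replicate 1. Falling immediate-early genes numbered 4 without control vehicle replicate 1 or control estradiol replicate 1, and falling cholesterol synthesis genes 6 without control vehicle replicate 1.

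In cyclin D1 siRNA, estradiol raised GREB1 10.4-fold (log2 3.38 ± 0.26 SE, n = 2 per group), MYBL1 6.95-fold (2.80 ± 0.26), CXCL12 6.31-fold (2.66 ± 0.26) and the neuropeptide Y receptor gene NPY1R 5.27-fold (2.40 ± 0.26). PSCA fell 5.83-fold (-2.54 ± 0.33), ISG15 4.13-fold (-2.05 ± 0.38), H1-4 3.91-fold (-1.97 ± 0.36) and CLDN4 3.77-fold (-1.92 ± 0.37). In all 714 genes passed, 307 higher and 407 lower. Of 45 estrogen-induced genes 27 rose and 1 fell, ANXA9 (-1.11 ± 0.27), or 32 and 2 adjusted over the list alone, with a median of 0.98 (camera adjusted p = 3.66e-24, adjusted p = 0.0322 with an estimated correlation). Of 30 estrogen-repressed genes 10 fell, EFNA1 (-1.91 ± 0.27) among them, and 2 rose, NR5A2 (2.03 ± 0.28) and RASGRP1 (1.75 ± 0.27), or 13 and 5 adjusted over the list alone. Their median was -0.48 (camera adjusted p = 2.00e-05, adjusted p = 0.0700 with an estimated correlation). Rising estrogen-induced genes numbered 12 without cyclin D1 vehicle replicate 1 and 23 without replicate 2, and 17 and 11 without cyclin D1 estradiol replicate 1 and 2, with medians of 0.92 to 1.05 in these fits. Falling estrogen-repressed genes numbered 4 without cyclin D1 vehicle replicate 1 and 5 without cyclin D1 estradiol replicate 2.

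Cell cycle lists also passed toward higher values with estradiol in cyclin D1 siRNA by camera with the preset correlation, and none of these 3 did with an estimated one. Of 50 DNA replication and E2F target genes 19 rose and 0 fell, with CDC45 at 1.55 ± 0.27 and the sliding clamp gene PCNA at 1.42 ± 0.27, or 35 and 1 adjusted over the list alone. Their median was 0.77 (camera adjusted p = 1.52e-19, adjusted p = 0.100 with an estimated correlation). Of 43 mitotic genes 5 rose and 0 fell, MAD2L1 (1.06 ± 0.28) and KIF2C (0.98 ± 0.26) among them, or 25 and 0 adjusted over the list alone. Their median was 0.72 (camera adjusted p = 2.22e-15, adjusted p = 0.386 with an estimated correlation). Of 24 DNA repair and checkpoint genes 6 rose and 0 fell, CHEK1 (1.18 ± 0.26) and TIPIN (1.14 ± 0.27) among them, or 10 and 0 adjusted over the list alone. Their median was 0.55 (camera adjusted p = 1.76e-06, adjusted p = 0.294 with an estimated correlation). Luminal epithelial genes had 5 of 18 lower, ERBB3 (-1.54 ± 0.28) and CLDN3 (-1.62 ± 0.30) among them, or 9 adjusted over the list alone. Their median was -0.67 (camera adjusted p = 2.82e-06, adjusted p = 0.312 with an estimated correlation). Of 36 interferon-stimulated genes 5 fell, ISG15 and BST2 (-1.44 ± 0.29) among them, or 10 adjusted over the list alone. Their median was -0.33 (camera adjusted p = 4.64e-06, adjusted p = 0.567 with an estimated correlation). Among D-type cyclin, CDK and CDK inhibitor genes 0 passed, CDKN1A standing at -0.65 ± 0.27 (list adjusted p = 0.726). The number of passing genes was 349 without either control vehicle array, 70 and 1607 without cyclin D1 vehicle replicate 1 and 2, and 444 and 88 without cyclin D1 estradiol replicate 1 and 2. GREB1, MYBL1, CXCL12, NPY1R, PSCA, NR5A2, RASGRP1 and EFNA1 kept their call in all of these fits, and the remaining 13 of 21 passing named genes did not. The interferon call was lost without cyclin D1 estradiol replicate 2 (median -0.04).

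The list counts in cyclin D1 siRNA moved with single arrays and with the axis of replicate differences as a covariate. With that covariate 11 estrogen-induced genes rose (median 0.98). Of the DNA replication (0.74), mitotic (0.48) and DNA repair genes (0.50) 0 rose. Of the luminal (-0.42) and interferon-stimulated genes (-0.13) 0 fell. The camera calls of these lists held. Without cyclin D1 vehicle replicate 2, which lay toward the estradiol arrays, 23 mitotic genes rose with estradiol (median 1.01) and 25 DNA replication genes (0.91), and without replicate 1 0 mitotic (0.43) and 1 DNA replication gene (0.73). Without cyclin D1 estradiol replicate 2 these counts were 0 (0.52) and 0 (0.73), and 2 mitotic genes rose without replicate 1 (0.87). Rising mitotic genes numbered 0 without either control vehicle array and 9 without either control estradiol array. DNA repair genes that rose numbered 0 without cyclin D1 vehicle replicate 1 or cyclin D1 estradiol replicate 2, and 2 without either control vehicle array or cyclin D1 estradiol replicate 1. Falling interferon-stimulated genes numbered 0 (median -0.12) and 12 (-0.66) without cyclin D1 vehicle replicate 1 and 2, and 11 (-0.76) and 1 without cyclin D1 estradiol replicate 1 and 2. They numbered 3 without either control vehicle array and 9 without either control estradiol array. Falling luminal genes numbered 0 (median -0.45) and 8 (-0.88) without cyclin D1 vehicle replicate 1 and 2, and 1 (-0.49) without cyclin D1 estradiol replicate 2.

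The estradiol responses under the 2 siRNAs, which share no array, overlapped. Of the 307 genes that rose in cyclin D1 siRNA 283 also rose in control siRNA, against 53.2 expected if genes were independent. Of the 407 that fell 351 also fell in control siRNA, against 75.6. Genes move together and both comparisons took each gene's spread from the same fit, so these expected counts are not chance levels. Of the genes that rose in control siRNA 94.2% had the same sign in cyclin D1 siRNA, and of those that fell 96.0% did. To set sizes side by side, the response in cyclin D1 siRNA was regressed on that in control siRNA, using one control replicate pair to correct for noise in the other, so that equal responses give a slope of 1. Over all genes the mean slope was 0.536, and it was 0.745 without cyclin D1 vehicle replicate 2 and 0.326 without replicate 1. Over the 45 estrogen-induced genes it was 0.851, and 0.916 and 0.786 without the same arrays.

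**Figure D3:**
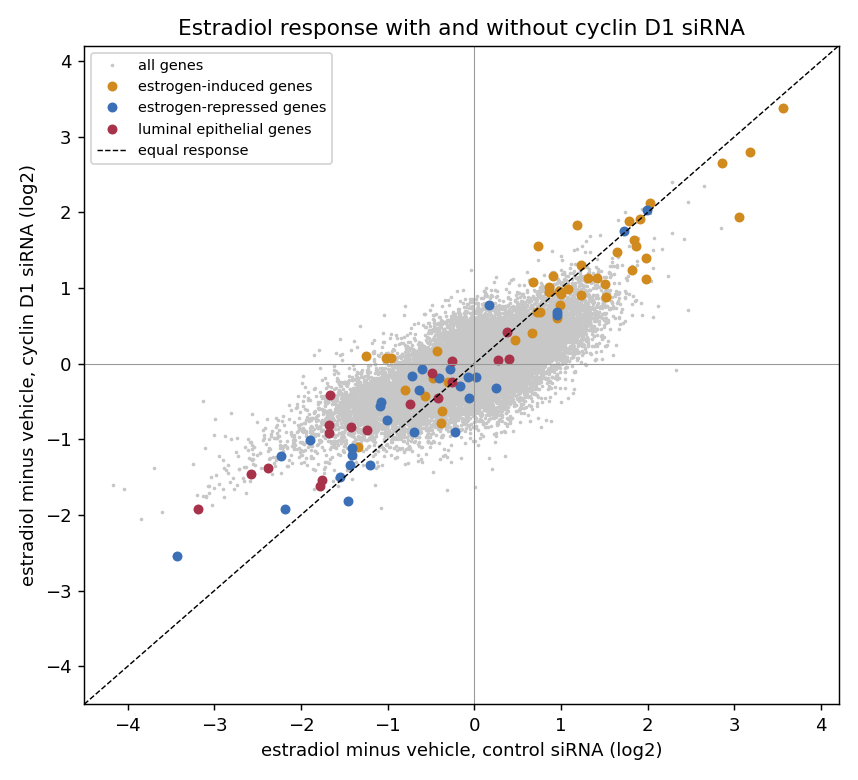
Log2 estradiol response (estradiol minus vehicle) of each of 18377 genes in control siRNA (horizontal) and cyclin D1 siRNA (vertical), means of 2 arrays per group, with 3 gene lists coloured and a dashed line where both are equal. GREB1 lay at 3.56 and 3.38, near the dashed line, while the slope over all genes was 0.536.

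Whether the estradiol response differed between the siRNAs was tested by the interaction, in which 2 of 18377 genes passed, both with a higher value in cyclin D1 siRNA, and 1972 had an unadjusted p under 0.05. The histone gene H3C7 had an interaction of 2.65 ± 0.46 SE (limma adjusted p = 0.0331, n = 2 per group). NDUFA13, a subunit of respiratory complex I, had 2.26 ± 0.40 (adjusted p = 0.0331). Quantile normalization or trend and robust moderation left 0 passing genes, while both genes passed with array weights, the replicate block or the highest-mean probe set. H3C8 (1.97 ± 0.38, adjusted p = 0.0720) did not pass, nor did the genes with the smallest p in the other direction, MSMB (-1.75 ± 0.39), CCDC149 (-1.60 ± 0.36) and RPS6KA5 (-1.59 ± 0.38). Estrogen-induced genes had a median interaction of -0.07 with 0 members passing, also adjusted over the list alone (camera adjusted p = 0.909), and GREB1 had -0.19 ± 0.37. CTSD (1.35 ± 0.46), RBM24 (-1.12 ± 0.40), XBP1 (1.03 ± 0.37) and IGFBP4 (a 2.14-fold difference) had the smallest p of that list and did not pass. DNA replication and E2F target genes had a median of 0.06, with MCM2 at 1.47 ± 0.39, CDT1 at 1.34 ± 0.37 and 0 passing, or 2 higher adjusted over the list alone (camera adjusted p = 0.238), and mitotic genes a median of -0.22 with 0 passing, also adjusted over the list alone (camera adjusted p = 0.101). These 2 lists moved with single arrays. Mitotic genes had a median interaction of 0.14 without cyclin D1 vehicle replicate 2, and passed at -0.54 without replicate 1 (camera adjusted p = 0.000225) and at -0.37 without cyclin D1 estradiol replicate 2 (camera adjusted p = 0.00533). DNA replication genes had -0.07 without cyclin D1 vehicle replicate 1, and passed at 0.17 without replicate 2 (camera adjusted p = 0.00388) and at 0.17 without cyclin D1 estradiol replicate 1 (camera adjusted p = 0.0346). With the axis of replicate differences as a covariate, both passed toward higher values, mitotic genes at 0.23 (camera adjusted p = 0.0175) and DNA replication genes at 0.20 (camera adjusted p = 0.000143). Since that axis was drawn from the residual spread of the same arrays, these p-values tend to be too small.

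The glycolysis (median 0.44), immediate-early and stress (0.35) and luminal epithelial lists (0.33) passed toward higher values in the interaction, with camera adjusted p = 0.000269, 0.0199 and 0.0102 and adjusted p = 0.636 for each with an estimated correlation. In each 0 members passed, and 5, 0 and 0 did adjusted over the list alone. All 3 lists fell with estradiol in control siRNA. The interaction subtracts that response on the same control arrays, so lists that fell there tend to take a positive interaction. The slope of 0.536 over all genes would act the same way with genes at large, but slopes differed between lists. Whether this accounts for the 3 calls was not tested. The leading members of the 3 lists were SLC2A1 (1.54 ± 0.43), a glucose transporter gene, ENO1 (1.41 ± 0.38), IER3 (1.22 ± 0.38) and the keratin gene KRT19 (1.25 ± 0.41), none of which passed. H3C7 and NDUFA13 lost their call without control vehicle replicate 1, without cyclin D1 vehicle replicate 2 and without either cyclin D1 estradiol array, and both the luminal and immediate-early calls were lost without control vehicle replicate 2 (0.33 and 0.45) or control estradiol replicate 1 (0.24 and 0.26). The luminal call was also lost without cyclin D1 estradiol replicate 1 (0.13) and with the axis of replicate differences as a covariate (0.10, camera adjusted p = 0.108). With that covariate the glycolysis median was 0.33 and the immediate-early one 0.10, and oxidative phosphorylation genes passed (0.14). Interferon-stimulated genes, with no pass on all arrays, passed in the interaction without control vehicle replicate 1 (0.12), control estradiol replicate 2 (0.17), cyclin D1 vehicle replicate 1 (0.35) or cyclin D1 estradiol replicate 2 (0.50). Cholesterol synthesis genes passed without control vehicle replicate 1 (0.39), control estradiol replicate 2 (0.54) or cyclin D1 vehicle replicate 1 (0.54), and oxidative phosphorylation genes without cyclin D1 vehicle replicate 2 (0.10) or cyclin D1 estradiol replicate 1 (0.19). The number of passing genes was 0 in 3 of the 4 fits in which H3C7 and NDUFA13 lost their call, and was 5 and 62 without control estradiol replicate 1 and 2, 192 without cyclin D1 vehicle replicate 1, and 9 with the probe set of highest mean centred value for each gene.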

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

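The tests on leukocytes, on the siRNA duplex and on the size of the estrogen-induced response were chosen after their results had been seen, as were the test of the axis of replicate differences within each treatment for the interferon-stimulated genes and the split that was left out of the count. The covariate for that axis was chosen after the data had been seen but before any fit with it, and the marks for its other tests and for the remaining tests were set before their results.

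The estradiol response differed between cyclin D1 and control siRNA, by the interaction, for H3C7 (2.65, adjusted p = 0.0331) and NDUFA13 (2.26, adjusted p = 0.0331), and for the luminal epithelial (median 0.33), glycolysis (median 0.44) and immediate-early and stress genes (median 0.35). None of the 3 lists passed with an estimated correlation (adjusted p = 0.636 each). All 3 fell with estradiol in control siRNA (medians -1.33, -0.60 and -0.70). The interaction subtracts the control response on the same arrays, so lists that fell there tend to take a positive interaction. The slope of one response on the other over all genes, 0.536, would act the same way with genes at large. Slopes differed between lists, and whether this accounts for the 3 calls was not tested. Neither H3C7 nor NDUFA13 passed with quantile normalization or with trend and robust moderation, each of which gave 0 genes. Both passed with array weights, the replicate block or the highest-mean probe set. With the axis of replicate differences as a covariate they did not pass. The 3 list medians were then 0.10 (camera adjusted p = 0.108, call lost), 0.33 and 0.10 (camera adjusted p = 0.0403). Among 9559 probe sets with several symbols or no gene listed, which enter no comparison in the report, 20 passed for the averaged cyclin D1 siRNA difference, 1244 for estradiol in control siRNA and 59 for estradiol in cyclin D1 siRNA.

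More genes passed for estradiol in control siRNA (6595) than in cyclin D1 siRNA (714), while 2 passed for the difference between these responses; with quantile normalization the counts were 5432 and 1519, so the size of the gap depends on scaling. Cyclin D1 vehicle replicate 2 lay toward the estradiol arrays on the first principal component. Its difference from replicate 1 correlated with the control estradiol response across genes (r = 0.579, genes not being independent replicates). That difference had a median of 0.54 over the mitotic and -0.32 over the luminal list, but -0.01 over the estrogen-induced list. Without that array the slope of one response on the other was 0.745 in place of 0.536. It came from 0.843 and 0.647 in the 2 replicate splits. Of these 1 met the mark against that array as the whole cause and the other met neither mark, so this stays open. The ratio of the counts fell from 9.24 to 0.0714 with the axis of replicate differences as a covariate (3 and 42 genes), as an array-wide axis would give, but that covariate itself ran with estradiol, from -1.26 and -0.81 in the control vehicle arrays to 1.39 and 0.64 in the control estradiol arrays, and raised the median SE of that comparison from 0.27 to 0.38. It left the estrogen-induced median there at 1.01 (0.99 without it) and GREB1 at 3.33 (3.56), but took the mitotic median from 0.97 to 0.32, the luminal one from -1.33 to -0.60 and the interferon one from -0.45 to 0.16, so an array-wide axis may account for the gap in counts without being shown to, and a weaker response of the estrogen-induced genes after cyclin D1 siRNA (slope 0.851) cannot be told apart from an equal one with 2 arrays per group.

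Interferon-stimulated genes were higher with cyclin D1 siRNA (median 0.89). Along the array-wide axis of replicate differences the siRNAs differed in opposite directions in vehicle and in estradiol. With that axis as a covariate both medians could not fall. The median went from 0.83 to 0.94 in vehicle and from 0.93 to 0.77 in estradiol. This argues against the axis as the whole source in estradiol only, and in vehicle the fit tests nothing. Single members then no longer passed, 0 in place of 4 in vehicle and 0 in place of 9 in estradiol. The averaged median says nothing here because the axis was balanced between the siRNAs. The 12 leukocyte genes, which include PTPRC and LYZ, had a median of -0.12 (interquartile range 0.39). In plates of 1 cultured cell line leukocytes were not a likely source, and signal over background is unknown. This test could therefore decide nothing. A response to this siRNA duplex, as double-stranded RNA can induce interferon-stimulated genes, cannot be told apart from loss of cyclin D1, because 1 siRNA was used for each group. The list was as high in estradiol (median 0.93), where CCND1 did not differ detectably, as in vehicle (0.83), which leaves both open.

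CCND1 was lower with cyclin D1 siRNA in vehicle and did not pass in estradiol. Exchanged labels among the 4 estradiol arrays are argued against by the other 76 genes called in vehicle, of which 48 lay apart in the same direction in estradiol without overlap of arrays (63.2%), where 1 in 6 would do so by chance. This rests on the risers, 40 of 41, since 8 of 35 fallers lay apart the same way and 10 the opposite way; an exchange of labels would act on both. With the axis of replicate differences as a covariate the CCND1 difference in estradiol was -0.36 ± 0.22 SE, between the marks set for and against that axis, and the one in vehicle was -0.99 and no longer passed (adjusted p = 0.189), so the axis cannot be told apart from the absence of one at this number of arrays. A lower starting level in estradiol, where CCND1 in control siRNA had itself fallen by 1.23 (0.44 and no pass with that covariate), stays open as a biological explanation and was not tested.

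For the averaged cyclin D1 siRNA difference, a model with treatment as a term gave 132 genes. This model can hold 34 splits of the 8 arrays into 4 and 4. Of these 1, the real one, gave as many, and the highest of the others gave 1 gene. Vehicle against estradiol is the treatment term itself and cannot be fitted beside it. That split gave 6126 genes without the term, which points to a structure of the samples. It was left out after its count had been seen. Counted as a split, 2 of 35 would have reached 132, a share past the mark for this test. The verdict turns on that choice, so no conclusion on chance is drawn.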

How the results depend on the processing

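The averaged cyclin D1 siRNA count stayed within 1.5 times of 211 under every setting chosen beforehand that kept all 8 arrays, and so did the estradiol count in control siRNA. The averaged lower calls (65) became 37 with quantile normalization and 108 with trend and robust moderation. The 1.5-fold minimum removed no passing gene, so it tests nothing. Counts below follow the order cyclin D1 siRNA in vehicle (77), in estradiol (53), estradiol in cyclin D1 siRNA (714) and interaction (2). Quantile normalization gave 19 (14 higher, 5 lower), 13, 1519 (787 higher, 732 lower) and 0. Of 43 list calls it kept 37 and lost 6, with 40 passing in all. Array weights gave 51, 107 and 286 for all but the last. Fitting only the groups compared gave 168 and 2 for the cyclin D1 siRNA comparisons, with fewer arrays to estimate the spread. Trend and robust moderation gave an interaction count of 0 (1972 genes at an unadjusted p under 0.05 without it). In vehicle it gave 53 higher and 14 lower against 41 and 36, sharing 46 of 77 genes. The highest-mean probe set gave 9. The replicate block gave 85 in estradiol and 9 in the interaction and moved no other count by over 1.5 times; deviations of same-numbered arrays correlated at -0.17 to 0.21, so the numbers are not taken to pair plates. Of 2 settings added after seeing the data, equal array medians gave 92 (69 higher, 23 lower) in estradiol and 9 in the interaction. The axis of replicate differences as covariate gave 1, 3, 42 and 0, and 3 for estradiol in control siRNA. There CTSD reversed to 0.32 and the interferon median turned from -0.45 to 0.16 without passing (camera adjusted p = 0.428). For trend, weights, block, equal medians and the axis the cause was not tested.

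Leaving out 1 array gave 41 to 272 genes for the averaged difference, 1 to 208 in vehicle, 11 to 154 in estradiol, 2424 to 7216 and 70 to 1607 for estradiol in control and cyclin D1 siRNA, and 0 to 192 for the interaction. CCND1 averaged ran from -0.86 to -0.52 and passed at -0.83 and -0.86. Of 43 list calls, 1 held with an estimated correlation and 15 were among the 16 passed by fry, which added D-type cyclin genes for estradiol in control siRNA (fry p = 0.0332, camera adjusted p = 0.209). Over the refits, which leave out these 2 tests, list calls stayed 610 times and were lost 35 times; named genes stayed 3942 times, lost a call 303 times, gained 61, moved 47 and reversed 1. The dim filter and pseudocount were not run, since centred log values hold no brightness, and signal over background is unknown.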

Other observations

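Histone genes were looked at as a group after H3C7, H3C8, H4C2 and H1-4, all members of it, had been seen among the genes that fell most, so no p-value is given for the group. Of 58 measured histone genes of the H1, H2A, H2B, H3 and H4 clusters 33 passed as lower and 0 as higher with estradiol in control siRNA (median log2 -0.76), and 3 as lower with estradiol in cyclin D1 siRNA (median -0.22). With cyclin D1 siRNA in vehicle 16 passed as lower and 0 as higher (median -0.61), while in estradiol 0 passed (median -0.03). The interaction had a median of 0.64, with 1 gene passing, H3C7. Many histone genes are similar in sequence, so single probe sets may read several of them, which was not checked. The mitotic list had a median of 0.97 with estradiol in control siRNA. No explanation was tested beyond the axis covariate, under which H3C7 had an interaction of 1.97 and did not pass.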
